A study of Mus musculus with 6 samples.

How the data were processed

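Cells freshly isolated from small-intestinal crypts of C57BL6 mice aged 10 weeks were profiled by Drop-seq, a droplet method in which each cell's polyadenylated RNA is tagged with a barcode of 12 bases and a molecular identifier (UMI) and read at its 3′ end. Mice lacking *Ptger4* in the epithelium (knockout) were compared with mice carrying the unrecombined floxed gene (flox), with 3 collections of droplets per genotype from 2 biological replicates. The labels do not state which collections share a biological replicate. Their codes were read as collections 1 and 2 of each genotype belonging to biological replicate 1 and collection 3 to biological replicate 2. Crypts were released with EDTA and dissociated with trypsin, per the labels' protocols.

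The deposited tables hold counts per gene and cell barcode, whole numbers that were not normalized. Reads were aligned with STAR 2.6 to the mouse build mm10, per the submitters' processing notes. The annotation release, the rule by which barcodes entered the tables, the settings for collapsing UMIs, the Cre driver and the deleted part of *Ptger4* are not given in the sources used here. Gene positions were taken from a GENCODE annotation of build GRCm38, in which 17963 of the 19178 symbols (93.7%) were found. That annotation may differ from the one used for counting.

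Barcodes with at least 300 detected genes and at most 25% mitochondrial counts were kept, which left 4890 of 13191 barcodes (37.1%). Counts were scaled to 10000 per cell and log-transformed, and 2000 highly variable genes (mitochondrial genes left out) gave 30 principal components. A graph of 15 nearest neighbours was weighted by shared neighbours and partitioned with the Leiden algorithm at resolution 1.0, without batch integration. This gave 18 clusters. A cluster was named from 14 marker lists when at least 3 of its class's markers were enriched at least 1.5-fold and detected in at least 10% of its cells, and when at least 2 of them were among its top 10 genes or at least 50% of the class's measured markers were enriched. The marker lists were fixed before the data were examined, as were the tests, the barcode filter and the gene lists, whereas the thresholds of the naming rule were set afterwards. It named 14 clusters in 9 classes and left 4 clusters, with 27.0% of kept cells, unnamed. Their share was 28.9% ± 8.97 of kept cells in knockout and 26.7% ± 1.55 in flox (SD, n = 2 biological replicates). Cells of the T cell or NK-like and B or plasma cell-like classes are called immune cells. All 4502 other kept cells are called epithelial, which includes the 1322 cells of the unnamed clusters. Scrublet marked 2 of 4890 barcodes as doublets and so did not work as a caller here, and doublets were not removed.

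Counts were summed per biological replicate, since cells are not replicates, and the 2 knockout sums were tested against the 2 flox sums. edgeR's quasi-likelihood test was used with TMM factors and filterByExpr at a minimum count of 10, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The same test was run in each class with at least 20 cells in each of the 4 sums, which were the stem cell-like, cycling-like, enterocyte-like and goblet-like classes. Class shares were compared by an exact two-sided permutation test, whose smallest p is 0.333 for 2 against 2 biological replicates and 0.1 for 3 against 3 collections. Shares of cells with a *Ly6a* UMI were taken after thinning each cell to 500 UMIs. The 95% intervals of shares are exact Clopper-Pearson intervals and cover counting error only.

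Of 32 lists, 18 were gene lists (reserve and fetal-like epithelium, YAP targets, cAMP-responsive genes, dissociation stress, Wnt targets, Notch pathway, prostaglandin pathway, quiescent stem cell, MHC class II, interferon response, antimicrobial, ion and fluid transport, sterol synthesis, apoptosis and p53, ribosomal protein, mitochondrially encoded, sex-linked and hemoglobin). The marker lists were those of intestinal stem, cycling, enterocyte, Paneth, goblet, enteroendocrine, tuft, T or NK, B or plasma, myeloid, fibroblast, endothelial, muscle and erythroid cells. Lists with at least 3 tested members were tested with limma's camera on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 26 lists that qualified. Members were also counted with p adjusted over the list alone.

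The named genes follow a rule fixed beforehand. In all kept cells these are *Ptger4* and *Ly6a*, plus up to 12 genes per direction with the largest change among those past the threshold, with a mean of at least 20 CPM and no overlap between the collections of both genotypes. Where fewer than 6 passed, genes with the smallest unadjusted p filled the number and are given as values. In each class the numbers were 5 and 3. Symbols made of Gm and a number, ending in Rik or containing -ps were counted as predicted genes and not named, and 1 gene selected by the rule is not reported here. From each list, the members with the smallest p serve as examples, with a number per list that was set after the data were seen.

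The procedure was tested on simulated counts with 200 changed genes. Over all kept cells (10342 genes tested) it recovered 6.06% of genes changed 1.5-fold, 41.5% of those changed 2-fold and 92.2% of those changed 4-fold, with 6 false calls among 10147 unchanged genes. For enterocyte-like cells (5698 genes tested) it recovered 1.59%, 32.8% and 87.5% at the same folds, with 2 false calls among 5510. In a simulation of the list test, 1 of 1 raised lists and 0 of 19 unchanged lists were called. Each gene was drawn independently there, so the simulation says nothing about lists whose members vary together.

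The alternatives covered DESeq2, another normalization, no filter on low counts, single collections as samples, replicate blocks, omission of each collection, other barcode filters, other Leiden resolutions, other thinning depths and other list tests. Further alternatives were added after the data were seen. These used cell barcodes shared between collections, which sorted the collections into 2 inferred sequencing runs: run 1 with flox collections 1 and 2 and knockout collection 1, and run 2 with flox collection 3 and knockout collections 2 and 3. The labels name no runs. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.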

Results

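The transcriptomes of crypt cells were counted in 6 Drop-seq collections, 3 per genotype. *Ptger4* encodes EP4, a prostaglandin E2 receptor that signals through cAMP, and the comparison asked how crypt cells differ when their epithelium lacks it. Total counts were 1716715, 1605533 and 2646093 in knockout collections 1 to 3 and 3146909, 1228337 and 2478447 in flox collections 1 to 3. The knockout collections kept 754, 703 and 981 cells with median counts of 1254.5, 1070 and 1224, and the flox collections 1053, 473 and 926 cells with medians of 1312, 1235 and 1471.5. The filter kept 73.0% of the barcodes of flox collection 1 and 16.1% of those of flox collection 2. It set no upper limit on counts. The largest kept barcode held 126037 counts in flox collection 1 (4.17% of its kept counts) and 104905 in flox collection 3 (4.94%). In the other collections the largest held 1.29% to 2.39%. Counts of *Xist*, the RNA that coats the inactive X chromosome, were 1584 and 1457 in the third collections of knockout and flox and at most 11 in the other collections. Each genotype therefore had a male biological replicate 1 and a female biological replicate 2. The edgeR p-values of the main test measure the spread between these 2 animals or pools per genotype. That spread includes the difference in sex, for which the main test had no term. The camera p-values compare the members of a list with the other genes at a fixed correlation and do not measure that spread.

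*Ptger4*, on chromosome 15 (5206661 to 5244187, GRCm38), was still counted in every collection. Its level was 17.4, 19.1 and 24.5 CPM in knockout collections 1 to 3 and 11.9, 13.6 and 15.1 CPM in flox collections 1 to 3. The log2 fold change was 0.69 (SE 0.28, n = 2 per genotype) and did not pass the test over all genes (edgeR adjusted p = 0.9996). Adjusted over the prostaglandin list alone, its p was 0.182. In goblet-like cells the value of *Ptger4* was 1.53 (SE 0.49, adjusted p = 0.999) and in enterocyte-like cells 0.64 (SE 0.55). A 3′ tag can lie outside the deleted part of a gene, so these counts check neither the labels nor the deletion.

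Across all kept cells, *Mt1* rose in the knockout and was the 1 gene of 10555 that passed the test. The number of genes passing was 35 with no filter on low counts and 3 with the biological replicate as a block. *Mt1* encodes metallothionein 1, a small protein that binds zinc and copper, and lies on chromosome 8 (94179082 to 94180327, GRCm38). Its level was 1199, 1167 and 1420 CPM in knockout collections 1 to 3 against 260, 248 and 311 CPM in flox collections 1 to 3. The log2 fold change was 2.23 (SE 0.20, n = 2 per genotype, edgeR adjusted p = 0.000344). The neighbouring *Mt2*, a second metallothionein gene at 94172664 to 94173568 and similar in sequence, had 75.5 CPM in knockout and 46.8 CPM in flox and did not pass (log2 fold change 0.69, SE 0.31). Within inferred run 1 the *Mt1* log2 fold change was 2.31 and within inferred run 2 it was 2.08. For *Mt2* it was -0.05 and 0.63. In epithelial cells *Mt2* was at 42.0, 47.0 and 109 CPM in knockout collections 1 to 3 and 44.0, 48.4 and 51.8 CPM in flox. Its higher mean thus rested on knockout collection 3 and not on run 2 as a whole.

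**Figure D1:**
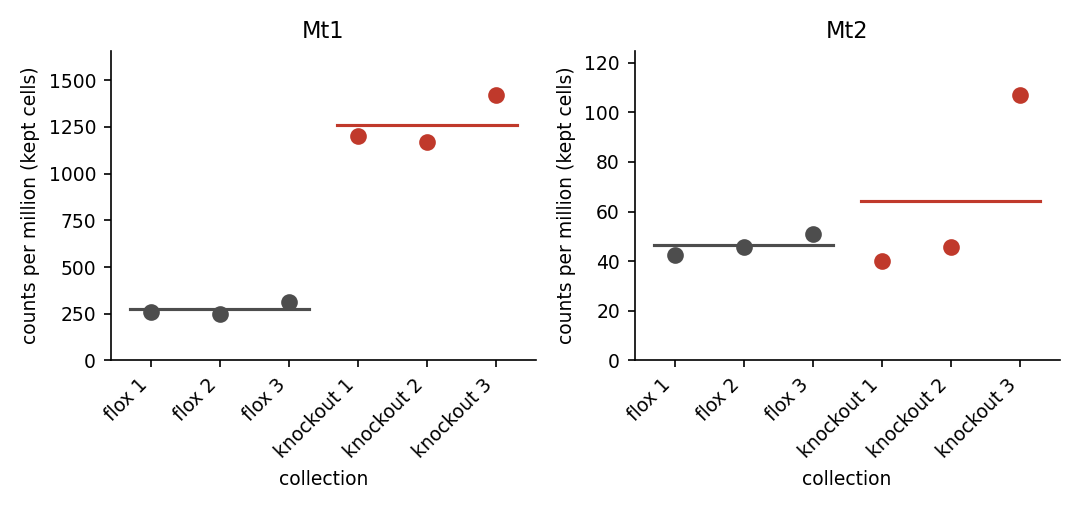
Level of *Mt1* (left) and *Mt2* (right) in CPM over kept cells, for each of the 3 flox (grey) and 3 knockout (red) collections, with lines at the mean of the collections. *Mt1* lies between 1167 and 1420 CPM in the knockout collections and between 248 and 311 CPM in the flox collections.

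No gene fell past the threshold in all kept cells (edgeR 0 lower, with 235 genes in either direction at an unadjusted p under 0.05, and DESeq2 16 higher and 0 lower). Those 235 are a smaller share of the tested genes than the 0.05 that would arise with no change at all. Such a share is no sign of further changes, but it cannot show that there were none. Among genes that did not pass, the values with the smallest p included hormone genes of enteroendocrine cells. *Pyy*, encoding peptide YY, had 32.8 CPM in knockout and 6.28 CPM in flox (log2 fold change 2.20), and *Gcg*, the proglucagon gene, 133 and 41.8 CPM (1.62). The collections of the genotypes overlapped, with *Pyy* at 5.87 CPM in knockout collection 2 and 25.3 CPM in flox collection 2, and *Gcg* at 93.7 CPM in knockout collection 3 and 160 CPM in flox collection 2. *Syt11*, a synaptotagmin gene, was at 1.46 on the log2 scale, and the small RNAs *n-R5-8s1* and *Vaultrc5*, a ribosomal and a vault RNA, at 1.03 and 0.89. Lower values were those of *Ms4a4b*, a T cell membrane protein gene (-3.21), *Mzb1*, a plasma cell gene (-2.14), *Dok3*, a signalling adaptor gene of B cells and myeloid cells (-1.93), *Zmym4* (-0.98), *Mptx2*, a Paneth cell pentraxin gene (-0.89), and *Apoe*, the apolipoprotein E gene (-0.78). *Mzb1* was 0.40 within inferred run 1.

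Enteroendocrine markers, genes of the hormone-secreting cells of the gut epithelium, rose as a list in the knockout (camera adjusted p = 4.18e-10). The call was lost with an estimated correlation (adjusted p = 0.971 with an estimated correlation). Of 13 tested markers 12 had higher values, with a median log2 fold change of 0.98. No marker passed over all genes (edgeR 0, DESeq2 0), 8 had an unadjusted p under 0.05, and 5 passed when adjusted over the list alone. With the biological replicate as a block *Gcg* (1.71) and *Cck* (1.92) passed over all genes, but neither did with the collection number as a block. *Fev*, a transcription factor gene of serotonin-producing cells, was at 2.11 (SE 0.68), *Cck*, encoding cholecystokinin, at 1.75 (SE 0.49), *Gcg* at 1.62 (SE 0.36) and *Cpe*, a prohormone-processing enzyme gene, at 1.39 (SE 0.40). The median was -0.05 within inferred run 1, with 1 biological replicate per genotype and 1 knockout collection, and 2.70 within inferred run 2, with 1 flox collection, and the difference between runs was not tested. The sums held all kept cells, with 60 enteroendocrine-like cells in knockout and 32 in flox. The list and the values of *Pyy*, *Gcg* and *Cck* were not separated from this number of cells. They and the share of these cells, given below, are not independent results.

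**Figure D2:**
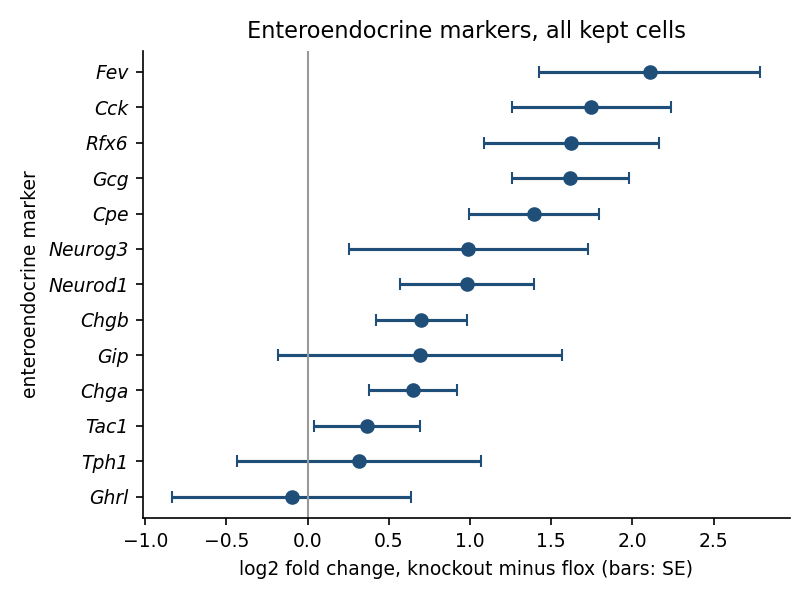
Log2 fold change (knockout minus flox) of the 13 tested enteroendocrine markers over all kept cells, from edgeR, with bars of 1 SE. 12 of 13 lie above 0, from *Fev* at 2.11 to *Tph1* at 0.32, and *Ghrl* lies at -0.10.

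None of the other 25 tested lists passed in all kept cells at the preset correlation. This depended on the model: the mitochondrially encoded list was called up with the biological replicate as a block. With single collections as samples it was called up too, and the Paneth list down. Targets of the pathway through which EP4 signals had a median log2 fold change of -0.08 in the cAMP-responsive list (19 tested, adjusted p = 0.788), with *Areg*, encoding the growth factor amphiregulin, at -0.47 and *Fos* at -0.25. The reserve and fetal-like list stood at 0.09 (14 tested, adjusted p = 0.911), with *Sprr1a* at -1.39, and YAP targets at 0.15 (9 tested, adjusted p = 0.911). Wnt targets stood at 0.11 (11 tested, adjusted p = 0.783), with *Ephb3* at 0.36 and *Axin2* at 0.19. The Notch list stood at 0.05 (10 tested, adjusted p = 0.788), with *Nrarp*, a Notch feedback gene, at -0.73 and *Atoh1*, the secretory lineage factor, at 0.61. The prostaglandin list stood at 0.03 (6 tested, adjusted p = 0.715) and the quiescent stem cell list at -0.19 (4 tested, adjusted p = 0.574). The ion and fluid transport list stood at 0.02 (11 tested, adjusted p = 0.867), sterol synthesis at -0.01 (15 tested, adjusted p = 0.911), and apoptosis and p53 at -0.12 (12 tested, adjusted p = 0.715).

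Among defence and stress lists, the interferon response stood at a median of 0.17 (11 tested, adjusted p = 0.295), with *Isg15*, an interferon-induced ubiquitin-like protein gene, at 0.89 and *Irf7* at 0.62. The antimicrobial list stood at 0.04 (12 tested, adjusted p = 0.696), with *Duoxa2* at 0.44 and *Lypd8* at 0.38, and MHC class II at 0.13 (8 tested, adjusted p = 0.295), with *Cd74* at 0.39 and *H2-DMb1* at 0.16. In the dissociation stress list (21 tested, median 0.08, adjusted p = 0.318), 2 members passed when adjusted over the list alone and 0 over all genes. These were the near-identical heat shock genes *Hspa1a* (1.05) and *Hspa1b* (0.99), whose reads can be shared and whose single values are uncertain. The ribosomal protein list stood at 0.06 (91 tested, adjusted p = 0.273). It was drawn up by symbol and holds *Rps3a2* (0.50), annotated as a processed pseudogene. Mitochondrially encoded genes stood at 0.23 (22 tested, adjusted p = 0.116), with *mt-Nd3*, a subunit gene of respiratory complex I, at 0.69 and *mt-Ta* at 0.92. Sex-linked genes stood at -0.05 (6 tested, adjusted p = 0.911).

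Of the marker lists, those of intestinal stem cells (median 0.08, 17 tested, adjusted p = 0.788), cycling cells (-0.07, 21 tested, adjusted p = 0.336), enterocytes (0.07, 20 tested, adjusted p = 0.788), goblet cells (0.12, 12 tested, adjusted p = 0.295) and tuft cells (0.11, 11 tested, adjusted p = 0.295) did not pass. Named examples were *Mcm5* (-0.41) and *Ube2c* (-0.28) for cycling cells, *Ccl6* (0.39) and *Tff3* (0.24) for goblet cells, and *Ltc4s* (1.15) and *Sh2d6* (0.999) for tuft cells. Paneth cell markers stood at a median of -0.25 (12 tested, adjusted p = 0.295), with *Lyz1*, the Paneth cell lysozyme gene, at -0.58, and the defensin genes *Defa21* at -0.55 and *AY761184* at -0.40, which share reads with near-identical copies and are uncertain. *Lyz1* and *Defa21* were at -1.65 and -2.02 within inferred run 1 but at 0.0094 and 0.0434 within run 2. Markers of T or NK cells stood at -0.15 (13 tested, adjusted p = 0.715), with *Gzmb* at -0.42 and *Ptprc* at -0.58. Those of B or plasma cells stood at -0.19 (10 tested, adjusted p = 0.273), with *Ighm* at -0.62. Of myeloid markers 1 was tested (0.67), and 0 of the fibroblast, endothelial, muscle, erythroid and hemoglobin lists.

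Within cell classes, *Mt1* rose in each of the 4 epithelial classes that could be tested. The log2 fold change was 1.76 (SE 0.20, edgeR adjusted p = 3.78e-05) in stem cell-like cells and 2.18 (SE 0.23, adjusted p = 2.26e-07) in enterocyte-like cells, the absorptive lineage. It was 2.31 (SE 0.28, adjusted p = 0.00535) in mucus-producing goblet-like cells and 2.002 (SE 0.32, adjusted p = 0.00218) in cycling-like cells, each with n = 2 per genotype. The *Mt1* call ended, with fold changes of similar size, in goblet-like cells without flox collection 1 (2.18), flox collection 3 (1.99) or flox biological replicate 1 (2.73). It also ended in cycling-like cells without knockout collection 1 (1.98) and within inferred run 1 (1.68), and in stem cell-like cells without knockout collection 3 (1.798).

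Of the 993 enterocyte-like cells, 514 lay in a cluster with 4 of 20 markers enriched, 289 of 516 in knockout and 225 of 477 in flox. In enterocyte-like cells 16 genes rose and 0 fell (edgeR, 6020 tested, 282 at an unadjusted p under 0.05, and DESeq2 15 higher and 0 lower). Besides *Mt1*, *mt-Nd3* rose by 1.43 on the log2 scale (SE 0.29, edgeR adjusted p = 0.0190), and the other 14 had symbols of predicted genes, 7 of them annotated as processed pseudogenes, with values from 0.998 to 2.53. The call for *mt-Nd3* held in 12 of 23 alternatives, over which its log2 fold change was 0.88 to 1.84. The number of calls was 3 with single collections as samples, 1 at 600 genes per barcode, 1 without knockout collection 2, 1 without flox collection 1, 27 without knockout biological replicate 1 and 53 without knockout collection 3. *Lrrc58*, at 1.18, did not pass (adjusted p = 0.0536), nor did *Slc16a10*, an amino acid transporter gene (-1.40), *Txlng* (-1.29) and *Areg* (-0.76, adjusted p = 0.188).

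The stem cell-like class was named from markers of crypt base stem cells, with 14 of 18 enriched in a cluster of 542 cells and 3 of 18 in a cluster of 470. The first, with median counts of 2629, held 222 knockout and 320 flox cells. The second, with median counts of 874.5, held 261 and 209. In stem cell-like cells 2 genes rose and 0 fell (edgeR, 6185 tested, 207 at an unadjusted p under 0.05, and DESeq2 2 higher and 0 lower), *Mt1* and 1 predicted gene. Omission of single collections or biological replicates gave 0 to 21 calls in stem cell-like, 0 to 2 in goblet-like and 0 to 9 in cycling-like cells. In goblet-like cells 1 rose and 0 fell (edgeR, 5979 tested, 110 at an unadjusted p under 0.05, and DESeq2 1 higher and 0 lower). In cycling-like cells 1 rose and 0 fell (edgeR, 1417 tested, 86 at an unadjusted p under 0.05, and DESeq2 1 higher and 0 lower). The genes at an unadjusted p under 0.05 were a share below 0.05 of those tested in stem cell-like and goblet-like cells and above it in cycling-like cells. In enterocyte-like cells this share was below 0.05 too, although genes passed there. Values that did not pass in stem cell-like cells were those of *AC123611.1*, a clone-based symbol (2.16), *Vaultrc5* (1.17), *Dpm2* (-1.36), *Abhd17c* (-1.66) and *Defa22* (-0.93). In goblet-like cells they were *Nme2* (1.03), *Vaultrc5* (0.90), *Triap1* (-1.35) and *Apobec3* (-1.63). In cycling-like cells they were *Mgst3*, a glutathione transferase gene (1.30), *Gapdh* (0.94), *Cdx1*, an intestinal transcription factor gene (-1.53), *Csnk2a1* (-1.51) and *Defa21* (-2.19). Defensin values are uncertain because of shared reads.

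Paneth markers fell as a list in 3 classes other than Paneth-like cells. The median log2 fold change was -0.53 in stem cell-like cells (camera adjusted p = 0.00159, and adjusted p = 0.824 with an estimated correlation) and -0.96 in cycling-like cells (adjusted p = 3.61e-05, and adjusted p = 0.868 with an estimated correlation). In enterocyte-like cells it was -0.35 (adjusted p = 0.0363, and adjusted p = 0.893 with an estimated correlation). In barcodes under 100 counts, which were taken to stand for free RNA without a test, Paneth markers took 7.03% ± 0.0543 of counts in knockout and 9.52% ± 2.03 in flox (SD, n = 2 biological replicates, exact permutation p = 0.333, the smallest possible). Flox collection 1 had only 14 such barcodes and knockout collection 3 only 29. Ribosomal protein genes rose in enterocyte-like (median 0.12, adjusted p = 0.00346, and adjusted p = 0.951 with an estimated correlation) and stem cell-like cells (0.09, adjusted p = 0.0156, and adjusted p = 0.824 with an estimated correlation). Mitochondrially encoded genes rose in enterocyte-like cells (0.35, adjusted p = 0.0303, and adjusted p = 0.951 with an estimated correlation). In stem cell-like cells the goblet list (0.32, adjusted p = 0.00526) and the enterocyte list (0.25, adjusted p = 0.0350) rose, each with adjusted p = 0.824 with an estimated correlation. The genotypes differed in their mix of the 2 stem cell-like clusters, and list changes in this class were not separated from that mix.

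The mix of cell classes was compared as shares of kept cells. Paneth-like cells, the antimicrobial cells of the crypt base, made up 1.67% ± 0.520 of knockout and 3.76% ± 0.429 of flox cells (SD, n = 2, exact permutation p = 0.333). Enteroendocrine-like cells made up 2.41% ± 0.379 and 1.20% ± 0.624 (exact permutation p = 0.333). Over single collections these differences had an exact permutation p of 0.1 each (n = 3 collections, which come from 2 biological replicates and are not independent). All these p-values are the smallest the designs allow, so neither difference could pass. By collection, Paneth-like shares were 1.19%, 1.42% and 2.04% in knockout and 4.56%, 2.96% and 3.46% in flox, with exact 95% intervals from 0.547% to 3.13% and from 1.63% to 5.999%. Enteroendocrine-like shares were 2.12%, 3.27% and 2.14% in knockout and 1.42%, 2.11% and 0.756% in flox. As shares of epithelial cells they overlapped, with 2.33% and 2.25% in knockout collections 1 and 3 and 2.54% in flox collection 2 (exact permutation p = 0.3 over collections). Within inferred run 1 the enteroendocrine-like difference was 0.353 percentage points and within run 2 it was 1.95, against -2.57 and -1.73 for Paneth-like cells. At 600 genes per barcode the Paneth-like difference was -0.926 percentage points instead of -2.09. In the larger Paneth-like cluster, which held 105 of the 133 cells, Paneth markers took a median of 1.60% of counts, close to the 95th percentile in immune cells (1.44%). The smaller cluster of 28 cells, with 13 of 13 markers enriched, held 0, 0 and 10 knockout and 8, 1 and 9 flox cells in collections 1 to 3.

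Other shares differed by less than the spread between biological replicates, or by about as much. Stem cell-like cells were 19.1% ± 4.87 of knockout and 21.5% ± 0.709 of flox cells, cycling-like cells 3.95% ± 0.824 and 4.25% ± 2.39, enterocyte-like cells 20.5% ± 4.90 and 19.7% ± 1.21, and goblet-like cells 15.5% ± 3.47 and 14.4% ± 3.06 (SD, n = 2). Tuft-like cells, chemosensory cells of the epithelium, were 1.38% ± 0.497 and 0.889% ± 0.423. T cell or NK-like cells were 2.51% ± 0.345 and 3.34% ± 2.13, and B or plasma cell-like cells 4.04% ± 2.83 and 4.44% ± 4.75. The exact permutation p was 0.667 for goblet-like and tuft-like cells and 1 for the others.

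**Figure D3:**
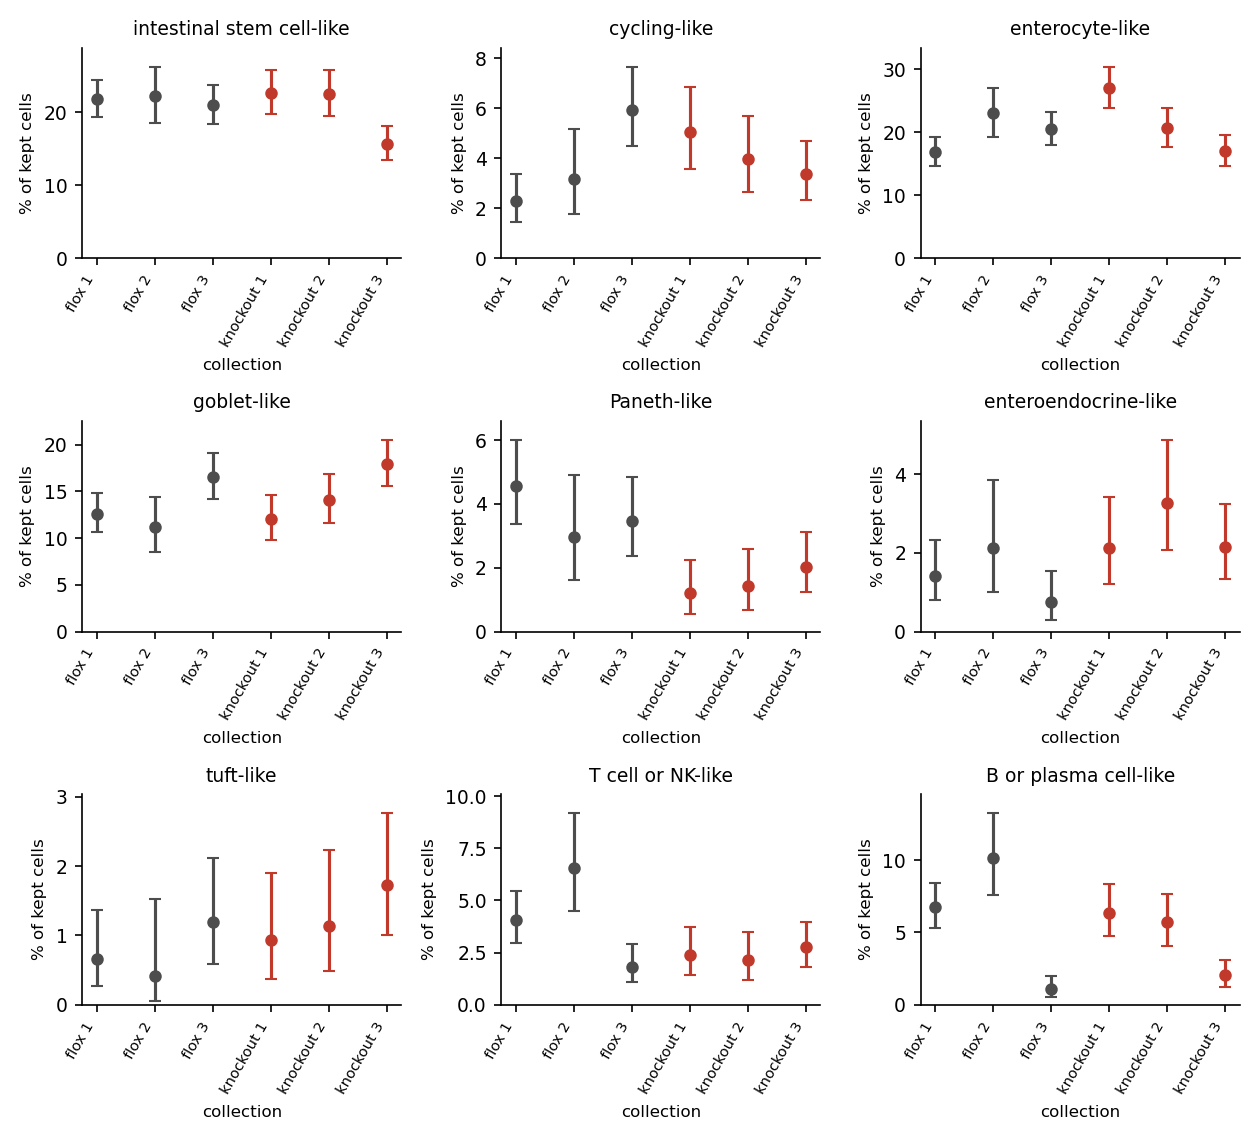
Share of kept cells in each named class (% of kept cells, from 0) for the 3 flox (grey) and 3 knockout (red) collections, with exact 95% Clopper-Pearson intervals that cover counting error only. Paneth-like shares are 1.19% to 2.04% in knockout and 2.96% to 4.56% in flox collections.

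*Ly6a* encodes Sca-1, a surface protein of reserve or regenerating epithelium and of lymphocytes. Its level over all kept cells was 13.9 CPM in knockout and 13.3 CPM in flox (log2 fold change 0.11, SE 0.32, edgeR adjusted p = 0.9996). After thinning to 500 UMIs, 8 of 2122 knockout and 10 of 2152 flox epithelial cells had a *Ly6a* UMI, with 148 and 80 shallower cells left out. The share per biological replicate was 0.372% ± 0.0421 in knockout and 0.497% ± 0.256 in flox (SD, n = 2, exact permutation p = 1). Unthinned shares were 2.24% and 2.03%. Within inferred run 1 the thinned share was 0.455% (3 of 660 cells) in the knockout and 0.333% (3 of 900) and 0.272% (1 of 367) in the flox collections. Within run 2 it was 0.342% (2 of 585) and 0.342% (3 of 877) in the knockout against 0.678% (6 of 885) in flox. These counts are too few to compare the runs. T cell or NK-like cells had 1.48% and B or plasma cell-like cells 6.19%, and Paneth-like cells 0 of 119 (median depth 826 UMIs against 1434 in epithelial cells). These lymphocytes can express *Ly6a* themselves and the Paneth-like cells are few and shallow, so the background of the epithelial share was not measured.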

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

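The tests of *Mt2*, of a transgene, of knockout collection 2 and of free Paneth RNA in a cluster were chosen only after the results were seen, as was every comparison by inferred run, and the tests of immune cells, ribosomal protein mRNA, read placement and the remaining Paneth explanations were written down before their values.

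*Mt1* was higher in all 3 knockout than in all 3 flox collections, and 3 explanations were weighed. Joint induction of the metallothionein genes by zinc, glucocorticoid or stress needs *Mt2* to move about as much, and its log2 fold change of 0.69, with an upper limit of 1.32 at 2 SE, lay below the lower limit of 1.83 for *Mt1*. This *Mt2* value averages over unlike collections, since only knockout collection 3 was raised, and it ranged from -0.068 to 1.20 over omissions. A source in the whole animal remains undecided: the *Mt1* excess in immune cells was 14.1% of that in epithelial cells (95% interval 8.39 to 21.8), within the 13.2% to 25.1% that free RNA brings for 5 enterocyte genes, but the immune log2 ratio of 2.95 met the opposite criterion. By the bound written beforehand this source would have been excluded, and that reading was given up after the values were seen: the 5 immune flox counts are themselves at the free RNA level, so that the same fold in immune cells would bring an excess of only 7.68%, within the bound as well. Immune *Mt1* counts were 11, 12 and 2 in knockout collections 1 to 3, against 1, 2 and 2 in flox. In the third collections this was 48.3 CPM in knockout and 52.2 CPM in flox. The immune excess and ratio therefore came from biological replicate 1. The 95% interval covers counting error of the knockout counts only, without the flox counts or the spread between replicates. Reads from a transgene, since some Cre constructs end in metallothionein sequence, were first read as compatible with similar fold changes over the classes (1.76 to 2.31), but they stay undecided, because added reads predict no constant fold, the excess ran from 722 CPM in stem cell-like to 2022 CPM in enterocyte-like cells (1.49 apart on the log2 scale), and the driver is not given in the sources used here; an effect of EP4 loss on *Mt1* itself stays open.

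Processed pseudogenes had higher values in the knockout in 81 of 87 tested, with a median log2 fold change of 0.55 (bootstrap 95% interval 0.47 to 0.65). For 8 of the 87 the collections of the genotypes did not overlap. The bootstrap resampled genes, so its intervals hold no spread between biological replicates. Over omissions of single collections the median was 0.21 to 0.75. More ribosomal protein mRNA is argued against, because ribosomal protein genes had a median of 0.063 (0.040 to 0.081) against 0.91 for their processed pseudogenes. Over omissions of single collections the ribosomal protein median was -0.098 to 0.22. The ribosomal protein set was drawn up by symbol and is not free of pseudogenes, since it holds *Rps3a2*, annotated as a processed pseudogene. A different placement of reads in the knockout collections stays open: pseudogene counts per 100 ribosomal protein counts overlapped between genotypes in immune cells and in failed barcodes (lowest knockout minus highest flox value, -0.648), first read as evidence against it, but they overlapped in epithelial cells too (-0.00317), so this measure decides nothing. Knockout collection 2 had 1.33 such counts in epithelial cells, against 0.408 to 0.634 in the other collections, and 1.58 in immune cells, but without it the median was 0.41, too high for it to carry the rise alone. Without flox collection 1 the median was 0.21, and it was 0.29 within inferred run 1 and 0.70 within run 2, so a difference between runs or collections may account for part of it, and no other biological explanation was tested.

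Paneth-like cells had lower shares in all 3 knockout collections, and whether this is a loss of Paneth cells cannot be told apart from 3 technical sources. For cells placed in other clusters, the share of kept cells with at least 5% of counts on Paneth markers overlapped between genotypes (gap -0.558 percentage points), with 22 such cells in each genotype, of which 6 flox and 10 knockout cells lay outside the Paneth-like clusters. For cells lost at the filter, the share among barcodes with at least 100 counts overlapped too (gap -13.6). Both were first read as compatible with these explanations and are given as undecided after the values were seen. The test of other clusters rests on 3 to 12 such cells per collection, too few to decide. In the test of the filter, barcodes under 100 counts already carried 6.44% to 10.97% Paneth counts, so the 5% limit may not separate cells from free RNA. For free RNA drawing shallow barcodes into the larger cluster, the median of 1.60% was under the 95th percentile of immune cells in flox (1.55% against 1.65%) and over it in knockout (1.71% against 0.992%).

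As shares of kept cells, 4 classes moved in opposite directions in the male and female biological replicates in every collection, differences that were not tested. The stem cell-like difference, knockout minus flox, was -5.25 percentage points in replicate 2 and 0.628 in replicate 1, which is -5.88 apart, and the cycling-like difference was -2.58 and 1.97, which is -4.55 apart. The stem cell-like reversal depends on the denominator. As a share of epithelial cells this class was lower in knockout in both replicates, at 24.6% against 25.1% in replicate 1 and 16.5% against 21.6% in replicate 2. The T cell or NK-like difference was 0.916 and -2.58, which is 3.50 apart, and the B or plasma cell-like difference was 0.959 and -1.76, which is 2.72 apart. The enterocyte-like difference was -3.49 in replicate 2 and 5.15 in replicate 1, which is -8.64 apart, but there the collections of the genotypes overlapped in replicate 1. Goblet-like, Paneth-like, enteroendocrine-like and tuft-like differences had the same sign in both replicates.

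Data outside the comparisons held 3 further signals. Knockout collection 1 and flox collection 1 shared 28 cell barcodes, where chance gives 0.209. Of the kept barcodes, 272 lay 1 base from a barcode with more counts in the same collection, where chance gives 4.52, and 119 of them were in knockout collection 1. In flox collection 3, 39.6% of barcodes with at least 100 counts had at least 5% of their counts on Paneth markers, against 8.24% to 23.8% in the other collections.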

How the results depend on the processing

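Settings that used inferred runs, shared barcodes, epithelial cells alone or males alone, and the 600-gene filter for lists, were chosen after the data were seen. Of 1873 alternative values for 88 results, 1684 kept their direction and side of the threshold or moved by less than the spread or, for counts, a factor of 1.5, 60 passed where the reported value had not, 20 no longer passed, 77 moved and 32 reversed. Class shares whose reported difference was within the spread, and the *Ly6a* share, were not counted as reversed when their sign changed. *Mt1* over all kept cells passed in all 23 alternatives (log2 fold change 2.08 to 2.39, adjusted p 1.10e-36 to 0.0461). The cause of the changes below was not tested. Fits that leave 1 sum in a genotype assume that it varies like the others, and the fits in males and in run 1 hold 1 biological replicate per genotype, so that their spread is between collections of the same replicate.

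With all kept cells, 1 gene was called, against 16 by DESeq2, 35 with no filter on low counts, 22 in run 1 and 12 in run 2. Omissions gave 1 to 34: 3 without flox collection 2, 33 without flox collection 3, 15 without knockout collection 3, 11 without knockout biological replicate 1 and 34 without flox biological replicate 1. Enterocyte-like calls, 16, were 3 with single collections, 1 with the run as a term, 7 at Leiden resolution 1.5, 1 at 600 genes, 2 at 10% mitochondrial counts, 3 in run 1 and 8 in run 2. Omissions gave 1 to 53: 1 without flox collection 1, 6 without flox collection 2, 10, 1 and 53 without knockout collections 1, 2 and 3, 27 without knockout biological replicate 1 and 7 without flox biological replicate 1.

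Stem cell-like calls, 2, were 1 with single collections, with the run as a term, at Leiden resolution 0.6, at 600 genes and at 10% mitochondrial counts, 16 with no filter and 10 in run 2. Omissions gave 0 to 21: 1 without flox collection 1, 18 without flox collection 3, 1 and 0 without knockout collections 2 and 3, 4 without knockout biological replicate 1 and 21 without flox biological replicate 1. Goblet-like calls, 1, were 5 in run 1 and 10 in run 2, and omissions gave 0 to 2: 0 without flox collection 1, flox collection 3 or flox biological replicate 1, and 2 without knockout collection 3. Cycling-like calls, 1, were 2 with single collections, 2 at 10% mitochondrial counts, 0 in run 1 (edgeR, 24 at an unadjusted p under 0.05) and 4 in run 2. Omissions gave 0 to 9: 2 and 4 without flox collections 1 and 3, 0 and 8 without knockout collections 1 and 3, and 9 without flox biological replicate 1.

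The numbers shared by the genotypes were not taken as pairs, since no label ties same-numbered samples together, although replicate 1 was male and replicate 2 female in both genotypes. Correlations of same-numbered deviations were -0.12, 0.04 and 0.36 for the 3 collections and 0.32 for the 2 biological replicates. With the biological replicate as a block, calls were 3 in all kept cells, 28 in enterocyte-like, 4 in stem cell-like, 2 in goblet-like and 3 in cycling-like cells, and 2 lists. The 3 in all kept cells were *Mt1*, *Gcg* (1.71) and *Cck* (1.92). Of the class values that did not pass in the report, *Lrrc58* (1.28), *Slc16a10* (-1.37) and *Areg* (-0.75) passed with this block in enterocyte-like cells and *Cdx1* (-1.56) in cycling-like cells. With the collection number as a block, calls were 1 in all kept cells (*Mt1*, without *Gcg* and *Cck*), 7 in enterocyte-like, 1 in stem cell-like, 2 in goblet-like and 1 in cycling-like cells.

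The enteroendocrine list kept its call in the other alternatives and lost it with an estimated correlation (adjusted p = 0.971), with fry (0.985) and in run 1 (0.156). Its adjusted p over omissions was 1.00e-15 to 0.00174. Lists called, 1, were 0 with an estimated correlation, 0 with fry, 3 with single collections, 8 in males, 4 in run 1, 4 in run 2 and 4 at 600 genes. Omissions gave 1 to 7: 5, 3 and 7 without flox collections 1, 2 and 3, and 3 and 6 without knockout collections 1 and 3. The mitochondrially encoded list was called up with the biological replicate as a block, with single collections, in males, in each run and without flox collection 1, knockout collection 1 or knockout collection 3. The Paneth list was called down with single collections, in males, in run 1 and without flox collection 1, flox collection 3 or knockout collection 3. T or NK markers were called down in 5 of these alternatives and up in run 2, and B or plasma cell markers down in 5.

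The Paneth-like difference, -2.09 percentage points, was -0.926 at 600 genes, -1.41 at 10% mitochondrial counts and -2.46 to -1.54 over omissions, with -1.54 without flox collection 1. The enteroendocrine-like difference, 1.21 percentage points, was 0.770 to 1.51 over omissions. The *Ly6a* share difference, -0.125, was 0.467 at 1000 UMIs and 0.208 unthinned. Over omissions its sign changed (-0.155 to 0.0561). So did that of the stem cell-like (-2.81 to 1.13), cycling-like (-0.609 to 1.39) and enterocyte-like differences (-1.29 to 4.29). The goblet-like (-1.32 to 3.30) and B or plasma cell-like differences (-3.76 to 1.60) changed sign too.

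Log2 fold changes that reversed, none past the threshold in the report, were as follows. In run 1 these were *Ly6a* -0.12, *Mzb1* 0.40, *Mt2* -0.047, *Hspa1a* -0.029, *Isg15* -0.29, *Atoh1* -0.29, *Axin2* -0.078, *Ccl6* -0.31, *Tff3* -0.15, *Cd74* -0.38, *H2-DMb1* -0.33 and *Vaultrc5* in goblet-like cells -0.59. In run 2 these were *Lyz1* 0.0094, *Defa21* 0.0434, *Gzmb* 0.19 and *Ptprc* 0.067. *Ly6a* was -0.036 and *H2-DMb1* -0.0518 with the run as a term, *Ly6a* -0.00610 at 10% mitochondrial counts and *Ptprc* 0.034 in epithelial cells alone. Over omissions, *Pyy* ranged from 1.49 to 3.76 and *Gcg* from 0.59 to 2.59, and neither reversed. *Ly6a* ranged from -0.16 to 0.35 (-0.10 without flox collection 1, -0.07 without knockout collection 2), *Mt2* from -0.068 to 1.20, *AY761184* from -0.80 to 0.017, *Defa21* from -1.57 to 0.054 (without knockout biological replicate 1), *mt-Ta* from -0.11 to 2.06, *Tff3* from -0.036 to 0.34, *H2-DMb1* from -0.11 to 0.39 and *Ptprc* from -1.26 to 0.22. Whether depth or the number of replicates limits these results was not tested, and in simulated counts of this design over all kept cells 41.5% of genes changed 2-fold were recovered.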

Other observations

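Cell barcodes recurred between collections, and all values on this point were computed only after the data were seen. Pairs among flox collections 1 and 2 and knockout collection 1 shared 21 to 28 barcodes, pairs among flox collection 3 and knockout collections 2 and 3 shared 9 to 18, and other pairs shared 0 to 2, where chance gives less than 1 barcode. Of 53 barcodes kept in 2 or more collections, 32 fell in the same cluster in every collection. Removing shared barcodes and those 1 base from a larger one took away 352 kept barcodes, with 7.36% of kept counts in all and 19.7% in knockout collection 1. After that removal, 1 gene was called over all kept cells, *Mt1*, and 17 in enterocyte-like cells.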
